A study of Mus musculus with 17 samples.

How the data were processed

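The samples were colon tissue from mice given intraperitoneal azoxymethane, a carcinogen that induces colon tumors in rodents. Kit-B6 denotes the C57BL/6 mice with normal Kit, and Kit-W/sh denotes the W-sash mice, in which an inversion upstream of Kit disturbs its expression and leaves adult animals short of mast cells. The W-sash inversion leaves the coding sequence of Kit intact, so the Kit amplicon reads the level of the transcript and does not test the genotype itself. Tumors were taken at postnatal week 32 from mice given 6 injections over 6 weeks and killed 18 weeks later. Preneoplastic colon was taken at postnatal week 14 from mice given 3 injections over 3 weeks and killed 3 weeks later. RNA was amplified with the QIAseq targeted mouse immuno-oncology panel, a multiplex PCR assay that reads short amplicons of chosen genes, and sequenced on a MiSeq, per the labels' protocols.

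The deposited values were whole-number counts per panel gene, 1 table per sample, and the authors' headers did not say whether they counted reads or molecular tags. The submitters' processing notes named the mm9 genome build and DESeq2 without a version or a role, and the aligner, counter and filters were not given in the sources used here. Amplicon coordinates were not given either, so no positions are printed. Each table held 993 entries, of which 988 were genes and 5 were genomic DNA control amplicons. The control amplicons had 0 counts in all 17 libraries and were left out of library sizes and tests, and 22 genes had 0 counts in every library. Genes were used under the symbols in the tables. Amplicons of near-identical relatives, such as the H2 (mouse MHC), Oas1 and Ceacam families, can capture one another's reads, and single members of these families are uncertain.

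Groups and replicate numbers came from the sample titles. Within every group, all pairs of libraries differed by more than counting noise, with a lowest chi-square per degree of freedom of 13.23, so no library was counted as a copy of another. The labels did not state that all samples of a group came from different mice, so p-values measure the spread between these samples. Counting floors and intervals cover counting error only, because amplified reads are not independent molecules. A floor of 3 counts corresponded to between 2.14 and 4.87 CPM (edgeR's size-scaled counts), depending on the library. These floors use unscaled library totals, whereas levels are given after the scaling described below, so the same count can differ slightly between them.

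All statistics were computed in R 4.3.3. Counts were tested with edgeR 4.0.16 (trimmed mean of M values (TMM) scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit, two-sided F test), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each genotype comparison was fitted on the libraries of its own stage. The stage comparisons within each genotype and the genotype-by-stage interaction came from 1 fit of all 17 libraries with 4 groups, in which all groups share 1 estimate of spread. Levels are given as CPM after TMM scaling, as mean ± SD, and changes as log2 fold change ± standard error. Stage was tied to age, number of injections, tissue and possibly sequencing run, and these cannot be told apart. Gene lists were tested with the fry test of limma 3.58.1 on voom-transformed log2 CPM from the same libraries, with Benjamini-Hochberg adjustment over the lists. The fry test asks whether the members of a list move on balance in 1 direction, and it does not compare the list with other genes. The camera test, used as an alternative, does compare the list with other genes, and an immune panel gives no neutral background for that. Of 28 lists of cell type and pathway genes, 2 (smooth muscle, and enteric neuron and glia) had no measured member. The panel measured 266 of the 566 genes on the lists, and 24 lists reached the minimum of 3 tested members in each comparison. The list of interstitial cell of Cajal and melanocyte genes had too few tested members, and the reference genes are given as values only. For mast cell genes, differences of mean log2(CPM + 1) between genotypes were also tested with two-sided exact permutation tests.

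The comparisons, lists, tests, most alternatives and the rule for naming genes were set before the data were examined. The rule took, for each comparison, Kit and the other mast cell genes, up to 12 higher and 12 lower genes with the smallest p among those past the threshold (or the 12 smallest p-values where fewer passed), up to 4 members with the smallest p from each list described, and the reference genes. The text names part of that set, and results that rest on certain genes are not reported here. Genes outside it (Car4, Srsf7, Emp1 and Mef2c) were chosen after their values were seen. The gene and list tests were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. At 4-fold, 93 were recovered in the tumor genotype comparison of 799 genes, 82 in the preneoplastic genotype comparison of 777 genes, 78 in the Kit-B6 stage comparison and 66 in the Kit-W/sh stage comparison, both of 869 genes. At 2-fold, the recovered genes numbered 69, 40, 48 and 40 in the same order, and unchanged genes called numbered 10, 5, 4 and 1. Of 4 lists shifted 2-fold, the list test recovered 4, 1, 4 and 3, with 1 unshifted list called in the Kit-B6 stage simulation. The simulated counts lacked the gene-specific extra variability that the quasi-likelihood fit estimates, so recovery in real data can be lower.

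The alternatives tried were relative log expression (RLE) scaling, unscaled library totals, size factors from reference genes, no count filter, DESeq2 1.42.0 in place of edgeR, the camera test with a preset correlation of 0.01 or an estimated correlation, fits on other sets of libraries, the sample number as a block, Kit-B6 tumors 4 and 5 summed (their deposited tables carried a shared code), and each library left out in turn. Reference-gene size factors rested on Tfrc and Rpl13a, the only reference genes measured. Size factors from the 9 genes listed after the control amplicons, the removal of 2 libraries that stood apart, and the use of some alternatives for the lists were chosen after seeing the data.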

Results

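Transcripts of 988 immune and tumor-related genes were counted in colon tumors and in preneoplastic colon of azoxymethane-treated mice, to compare animals with mast cells (Kit-B6) and mast cell-deficient animals (Kit-W/sh). There were 6 Kit-B6 tumors, 6 Kit-W/sh tumors, 3 Kit-B6 preneoplastic samples and 2 Kit-W/sh preneoplastic samples. Library totals were 616554 to 1399902 counts in Kit-B6 tumors, 1049408 to 1262171 in Kit-W/sh tumors, 616009 to 703549 in Kit-B6 preneoplastic colon and 621141 to 815973 in Kit-W/sh preneoplastic colon. Between 886 and 922 genes had a count in each library. Across all libraries the first principal component carried 61% of the variance and separated the preneoplastic samples (28.8 to 34.3) from the tumors (-24.9 to 8), with Kit-B6 tumor 4 lying nearest to the preneoplastic samples.

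Kit, the receptor for stem cell factor on which mast cells depend, had a lower average in Kit-W/sh than in Kit-B6 samples at both stages. In tumors its level was 93.7, 331, 137, 473, 169 and 124 CPM in Kit-B6 samples 1 to 6, and 77, 258, 48.9, 99.5, 83.1 and 67.8 CPM in Kit-W/sh samples 1 to 6. In preneoplastic colon it was 268, 343 and 521 CPM in Kit-B6 and 127 and 113 CPM in Kit-W/sh. Kit is also on the list of interstitial cell of Cajal and melanocyte genes, so its level does not measure mast cells alone. The library with the highest Kit, Kit-B6 preneoplastic sample 3, had 1.55 CPM of Cpa3. The mast cell carboxypeptidase Cpa3 was at 11.3 to 256 CPM in Kit-B6 tumors, at 0 to 9.81 CPM in 5 of the Kit-W/sh tumors and at 460 CPM in the library labelled Kit-W/sh tumor 2. That library also had the highest Tpsab1 (mast cell tryptase) and Ms4a2 (a chain of the IgE receptor) of the 17, at 54 and 27.8 CPM, against its label. The name "the library labelled Kit-W/sh tumor 2" is therefore kept throughout, and every tumor average for Kit-W/sh includes it unless stated. In preneoplastic colon Cpa3 gave 10 counts over the 3 Kit-B6 libraries and 0 in both Kit-W/sh libraries, all near the floor of 3 counts per library.

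The genotype difference of mean log2(CPM + 1) in tumors was -1.04 for Kit (exact permutation p = 0.0693, n = 6 and 6) and -2.55 for Cpa3 (exact permutation p = 0.113). On the CPM scale Cpa3 averaged 79.4 ± 186 in Kit-W/sh and 76.3 ± 93.4 in Kit-B6 tumors and its edgeR log2 fold change was 0.06 ± 1.39, with most Kit-W/sh counts in the library labelled Kit-W/sh tumor 2. For the tryptase Tpsb2 it was -1.25 (exact permutation p = 0.29) and for Tpsab1 -0.81 (exact permutation p = 0.61). Ms4a2 gave -0.32 (exact permutation p = 0.74) and the chymase Cma1 -0.20 (exact permutation p = 0.768). The transcription factor Gata2 gave -0.32 (exact permutation p = 0.478) and the prostaglandin D synthase Hpgds -0.58 (exact permutation p = 0.195). Hdc, which makes histamine and is also expressed by myeloid cells, had the opposite sign. Its level was 175 ± 75.6 CPM in Kit-W/sh tumors against 68.4 ± 28 CPM in Kit-B6 tumors. The log2 difference was 1.34 (exact permutation p = 0.00433, adjusted over the 9 mast cell genes p = 0.039). The smallest p that 6 against 6 samples allow is 0.00216. In preneoplastic colon Kit differed by -1.59 (exact permutation p = 0.1), and 0.1 is the smallest p that 3 against 2 samples allow. Of the 7 mast cell genes tested with edgeR in tumors, 0 passed over all genes and 1 (Hdc) passed adjusted over the list alone, and the list as a whole gave a fry adjusted p of 0.631.

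**Figure D1:**
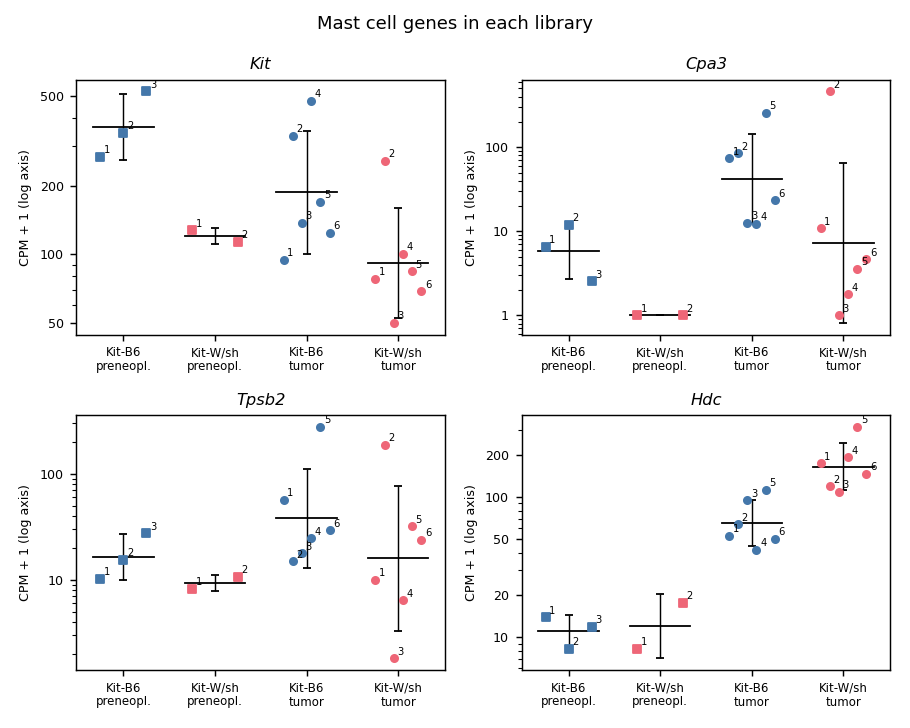
Levels of the mast cell genes Kit, Cpa3, Tpsb2 and Hdc in each of the 17 libraries, as CPM + 1 on log axes (points, libraries numbered by replicate; lines, mean of log2 values; bars, ±1 SD). The library labelled Kit-W/sh tumor 2 had 460 CPM of Cpa3, while the other 5 Kit-W/sh tumors had 0 to 9.81 CPM.

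Neutrophil and inflammatory genes were among the 12 genes with the smallest unadjusted p between genotypes in tumors, although none passed the adjustment. Cxcl2, a neutrophil chemokine, averaged 2258 ± 1675 CPM in Kit-W/sh tumors and 425 ± 282 CPM in Kit-B6 tumors. It lay above the Kit-B6 median in 6 of 6 Kit-W/sh tumors (log2 fold change 2.38 ± 0.61). Its receptor Cxcr2 averaged 243 ± 108 against 85.4 ± 28.9 CPM (1.49 ± 0.34). The formyl peptide receptor Fpr1 averaged 79.3 ± 32.9 against 22.1 ± 10.9 CPM (1.81 ± 0.48) and the macrophage chemokine Ccl4 203 ± 136 against 48 ± 26.5 CPM (2.06 ± 0.51). Nos2 (inducible nitric oxide synthase) differed by 1.56 ± 0.40, Gzmb (granzyme B) by 1.07 ± 0.28, the TNF receptor Tnfrsf1b by 0.70 ± 0.16, Rgs16 by 1.396 ± 0.3787 and Hells by 0.80 ± 0.22. On the lower side in Kit-W/sh tumors, the heparan sulfate proteoglycan Gpc4 was at 688 ± 63.8 against 1032 ± 179 CPM (-0.60 ± 0.13) and the transcription factor Zeb1 at 123 ± 21.7 against 200 ± 42.5 CPM (-0.71 ± 0.19).

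None of these genes passed the adjustment. Each had an adjusted p of 0.154, and edgeR called 0 of 799 genes, while 109 genes had an unadjusted p under 0.05 where 40 were expected by chance. DESeq2 called 27 genes, 20 higher and 7 lower, including Cxcr2, Cxcl2, Ccl4, Gzmb, Fpr1, Nos2, Il1a, Il1b, Gpc4, Zeb1 and Erbb2, and gave 182 genes no adjusted p. Cxcr2, Ccl4 and Gzmb were among 5 genes whose groups did not overlap (0.626% of genes, against 0.216% by chance). Kit-B6 tumor 4 had the lowest level of its group for these neutrophil genes, at 29.8 CPM for Cxcr2 and 39.1 CPM for Cxcl2.

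Among the gene lists, all 8 tested neutrophil genes were on the higher side in Kit-W/sh tumors, with a median log2 fold change of 1.56, and Cxcl1 was at 1771 ± 1184 against 428 ± 228 CPM. Over all genes 0 neutrophil genes passed and adjusted over the list alone 7 passed. The list gave a fry adjusted p of 0.195 and a camera adjusted p of 0.613 with an estimated correlation. Of the 10 inflammatory cytokine genes 9 were on the higher side, among them Il1b at 2324 ± 1610 against 608 ± 339 CPM, Il1a at 446 ± 284 against 111 ± 63.4 CPM and Csf2 at 59.8 ± 44.3 against 14.7 ± 7.6 CPM. Here 0 genes passed over all genes and 5 adjusted over the list alone (fry adjusted p = 0.195). All 5 growth signalling genes were on the lower side, led by the receptor Erbb2 at 461 ± 53.5 against 769 ± 275 CPM (-0.75 ± 0.21), with 0 passing over all genes and 1 adjusted over the list alone (fry adjusted p = 0.195). In all, fry called 0 of 24 lists and 3 had an unadjusted p under 0.05. The camera test with a preset correlation called 4 (neutrophil, inflammatory cytokine, chemokine ligand and growth signalling) and with an estimated correlation 0.

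At the preneoplastic stage, several genes induced by interferon had lower averages in the 2 Kit-W/sh samples than in the 3 Kit-B6 samples. Irf7, the transcription factor that amplifies type I interferon production, was at 1078 ± 116 CPM (n = 2) against 4468 ± 585 CPM (n = 3), a log2 fold change of -2.07 ± 0.20. It was the only gene of 777 called by edgeR (adjusted p = 0.0237), and both Kit-W/sh samples lay below all 3 Kit-B6 samples. The antiviral 2'-5' oligoadenylate synthetases Oas2 and Oas3 were at 138 ± 0.115 against 1097 ± 625 CPM (-3.02 ± 0.63) and at 150 ± 31 against 971 ± 421 CPM (-2.72 ± 0.46). The nuclear body protein Sp100 differed by -1.43 ± 0.24 and B2m, the light chain of MHC class I, by -0.85 ± 0.19. On the higher side, the neutrophil chemokines Cxcl5 and Cxcl1 were at 336 ± 105 against 53.6 ± 29.7 CPM (2.63 ± 0.55) and at 239 ± 129 against 42.1 ± 20.5 CPM (2.49 ± 0.56). Nfkbia, an inhibitor of NF-kB that NF-kB induces, was at 3094 ± 219 against 1762 ± 215 CPM (0.79 ± 0.17).

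These other genes had adjusted p-values of 0.228 to 0.2535 and did not pass. At an unadjusted p under 0.05 there were 83 genes against 39 expected by chance, and DESeq2 called 20, of which 3 (Cxcl5, Cxcl1 and Nfkbia) were higher and 17 lower, including Irf7, Oas3, Oas2, Sp100, B2m and Kit. The groups did not overlap for 231 genes (29.7%, against 20% by chance). The fold of Irf7 held with unscaled library totals (-2.04 ± 0.23, adjusted p = 0.0553) and with size factors from the 9 last-listed genes (-2.23 ± 0.25, adjusted p = 0.0812), but its call ended there. The call also ended in the fit of all 17 libraries, and without Kit-B6 sample 3 or either Kit-W/sh sample, while 16 genes were called without Kit-B6 sample 1. B cell genes varied among these samples, with a mean log2 level of 5.22, 8.51 and 7.35 in Kit-B6 samples 1 to 3 and 5.98 and 5.22 in Kit-W/sh samples 1 and 2. Oas2 was at 376, 1429 and 1485 CPM in the same Kit-B6 samples.

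Of the 19 tested interferon response genes, 11 were on the lower side in Kit-W/sh preneoplastic colon. Over all genes 1 was called lower, adjusted over the list alone 4 were lower and 1 higher, and the list had a fry adjusted p of 0.43. Of the neutrophil list (10 genes measured), the 3 tested genes were the chemokines Cxcl5, Cxcl1 and Cxcl2, all on the higher side. Cxcl2 had 25 counts in Kit-W/sh and 3 in Kit-B6 libraries (ratio 11.3, 95% exact interval 3.46 to 58.7, counting error only). No receptor gene of the list was tested, so these chemokines do not measure neutrophils themselves. Over all genes 0 of these passed and adjusted over the list alone 3 passed (fry adjusted p = 0.13). The Toll-like receptor and NF-kB list, with Nfkbia and Cd14 on the higher side and Tlr7 and Tlr3 on the lower, had a fry adjusted p of 0.13 with 0 genes passing over all genes and 1 adjusted over the list alone. The apoptosis and p53 list (Tnfrsf10b, Bcl2, Casp8 and Casp1 with the smallest p) had a fry adjusted p of 0.154. The fry test called 0 of 24 lists, with 3 at an unadjusted p under 0.05. Camera with a preset correlation called the neutrophil and chemokine ligand lists, which share Cxcl5, Cxcl1 and Cxcl2, and with an estimated correlation 0. With unscaled library totals fry called 1 list, type 17 immunity. For type 17 immunity the median log2 fold change (-0.27) and the mean (0.24) differed in sign.

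**Figure D2:**
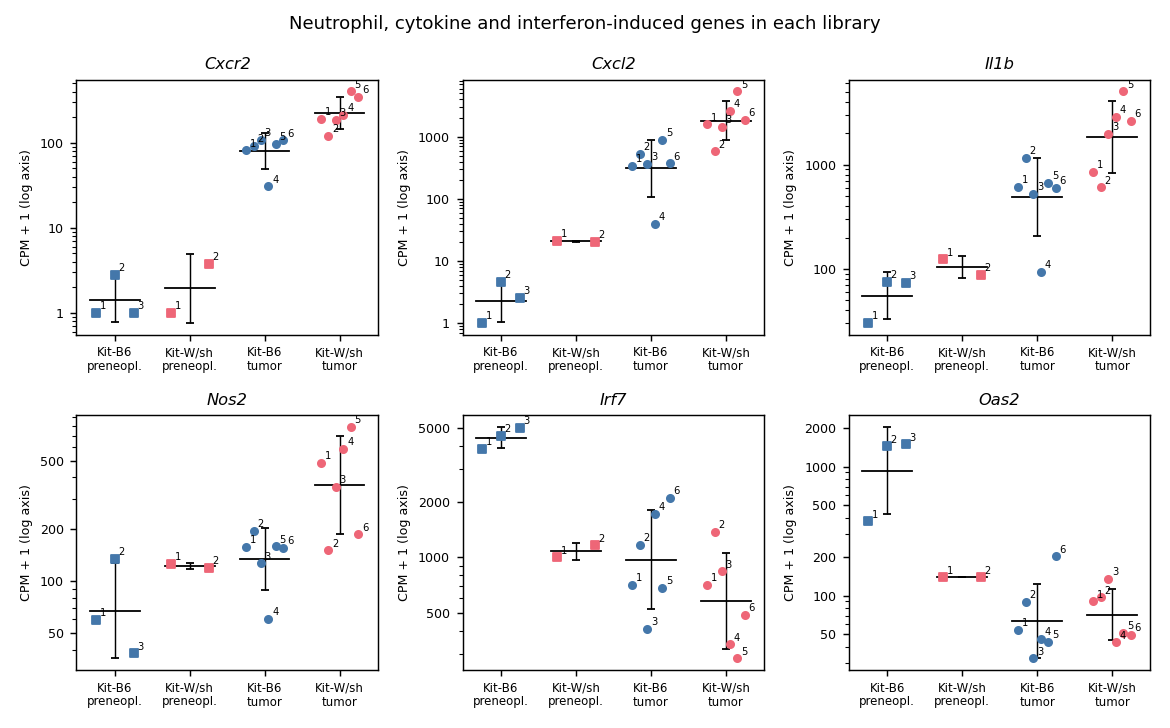
Levels of neutrophil, cytokine and interferon-induced genes in each of the 17 libraries, as CPM + 1 on log axes (points, libraries numbered by replicate; lines, mean of log2 values; bars, ±1 SD). Irf7 was at 3852 to 5016 CPM in Kit-B6 preneoplastic samples and at 996.5 and 1160 CPM in Kit-W/sh preneoplastic samples.

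In Kit-B6 mice, tumors differed from preneoplastic colon in many myeloid, interferon-induced and antigen presentation genes. The matrix protein Spp1 (osteopontin) rose from 6.56 ± 5.37 CPM (n = 3) to 1284 ± 717 CPM (n = 6), a log2 fold change of 7.54 ± 1.01 (edgeR adjusted p = 6.082e-05). Arginase Arg1, a product of suppressive myeloid cells, rose by 6.67 ± 0.76 and the neutrophil chemokine Cxcl5 by 6.45 ± 0.74. The transcription factor Nfe2l3 rose by 5.57 ± 0.59, Wfdc18 by 4.62 ± 0.54, Neto2 by 4.30 ± 0.50, the metalloreductase Steap4 by 4.03 ± 0.46, the transporter Abcc4 by 4.01 ± 0.38 and Fam3c by 2.36 ± 0.25. Trat1, a T cell receptor adaptor, fell by 6.79 ± 0.53 from 341 ± 181 to 3 ± 1.67 CPM (adjusted p = 4.76e-07). Further genes that fell were Oas1g (by 4.43 ± 0.43), Oas1b (by 3.88 ± 0.47), Oas2 (by 3.84 ± 0.54) and H2-Q1 (by 3.44 ± 0.51). The same held for H2-T24 (by 3.05 ± 0.38), Lime1 (by 2.69 ± 0.35), B2m (by 1.90 ± 0.27), Zc3h7a (by 1.51 ± 0.19), Atf4 (by 1.48 ± 0.21) and Tbk1 (by 0.91 ± 0.13).

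The named genes changed in the same direction in 6 of 6 tumors relative to the preneoplastic median. In all, edgeR called 357 of 869 genes, 193 higher and 164 lower in tumors, 253 of them by at least 2-fold, and DESeq2 called 402 (219 higher and 183 lower). For 255 genes the groups did not overlap (29.3%, against 2.38% by chance). The share of calls on the higher side was 54.1% and depended on the scaling, being 73% with unscaled library totals (273 higher, 101 lower), 66.1% with reference genes (162 and 83) and 62.6% with the 9 last-listed genes (216 and 129). Of the mast cell genes, Hdc rose by 2.72 ± 0.49 (adjusted p = 0.000526), and Kit (-0.77 ± 0.52) and Cpa3 (3.68 ± 2.15) did not pass. Mast cell list counts were 1 of 8 over all genes and 1 adjusted over the list alone (fry adjusted p = 0.427).

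Grouped by list, neutrophil genes rose in Kit-B6 tumors: 8 of 9 tested members over all genes and 9 adjusted over the list alone. Cxcl5 went from 53.6 ± 29.7 to 4648 ± 2158 CPM and Csf3r, the receptor for granulocyte colony-stimulating factor, from 7.54 ± 1.5 to 89.5 ± 35.5 CPM. Cxcr2 had 522 counts in the tumors and 1 in preneoplastic colon (ratio 148, 95% exact interval 26.5 to 5870). MHC class I genes fell (8 of 15 over all genes, 8 adjusted over the list alone), with B2m going from 49790 ± 3174 to 13330 ± 3583 CPM and H2-Q2 and the immunoproteasome gene Psmb9 lower by 2.19 ± 0.49 and 1.48 ± 0.41. Interferon response genes fell (10 lower and 1 higher of 20 over all genes, 10 and 1 adjusted over the list alone), including Oas1a (by 2.81 ± 0.43) and Irf1 (by 1.28 ± 0.22), while Ifitm3 rose by 2.11 ± 0.36. B cell genes fell (5 of 11 over all genes, 9 adjusted over the list alone), with Cd22, Bank1, Ms4a1 (CD20) and Pax5 lower by 2.96 ± 0.76, 2.38 ± 0.79, 3.49 ± 1.23 and 3.70 ± 1.35. These B cell genes varied widely within groups: Ms4a1 was at 247 CPM in Kit-B6 tumor 2 and at most 7.35 CPM in the other 5 Kit-B6 tumors. MHC class II genes fell (5 of 8 over all genes, 6 adjusted over the list alone), with H2-Aa lower by 1.83 ± 0.40 and Cd74 by 1.32 ± 0.42. In the eosinophil and basophil list Siglecf and Ccr3 fell (2 of 5 over all genes, 2 adjusted over the list alone), from 44.8 ± 19.7 to 7.55 ± 3.58 CPM and from 21.4 ± 7.05 to 4.61 ± 1.63 CPM.

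The fry adjusted p was 0.0046 for MHC class I, 0.0046 for interferon response, 0.0102 for B cells, 0.0138 for MHC class II, 0.0173 for neutrophils and 0.0221 for eosinophils and basophils, 6 called lists of 24. The camera adjusted p with an estimated correlation was 0.853 for the MHC class I, interferon response, B cell, MHC class II and neutrophil lists. For the eosinophil and basophil list the camera adjusted p was 0.886. The number of called lists was 0 with reference-gene scaling (Tfrc and Rpl13a only), 3 in a fit of the Kit-B6 groups alone, 0 without preneoplastic sample 2 and 12 without tumor 4. Just short of a call were cytotoxic lymphocyte genes (6 of 13 lower over all genes, 6 adjusted over the list alone, fry adjusted p = 0.0602) and monocyte and macrophage genes (9 higher and 1 lower of 16 over all genes, 12 and 1 adjusted over the list alone, fry adjusted p = 0.0616). The epithelial gene Epcam was at a log2 fold change of 0.02 ± 0.16 (adjusted p = 0.911).

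In Kit-W/sh mice, the tumors showed a myeloid rise against the 2 preneoplastic samples. Arg1 went from 16.4 ± 0.167 CPM (n = 2) to 2766 ± 1004 CPM (n = 6), a log2 fold change of 7.39 ± 0.96 (edgeR adjusted p = 0.000136). The alarmin Il33 rose by 4.93 ± 0.68, Wfdc18 by 4.58 ± 0.64, Csf3r by 4.31 ± 0.62 and Neto2 by 4.12 ± 0.60. Smaller rises were those of Hdc by 3.84 ± 0.60, Abcc4 by 3.46 ± 0.44, Ifitm3 by 3.31 ± 0.46, the insulin-like growth factor binding protein Igfbp5 by 3.10 ± 0.45, Lpcat4 by 3.01 ± 0.41 and Fam3c by 2.26 ± 0.30. Cxcr2 had 1763 counts in the tumors and 2 in preneoplastic colon (ratio 152, 95% exact interval 42.1 to 1260). Trat1 fell by 5.42 ± 0.51 from 247 ± 19.7 to 5.62 ± 2.84 CPM (adjusted p = 8.464e-06). Also lower were H2-Q1 (by 3.34 ± 0.55), Oas1g (by 3.23 ± 0.44), the efflux transporter Abcg2 (by 2.53 ± 0.43), Lime1 (by 2.21 ± 0.38), Irf1 (by 1.77 ± 0.25), Zc3h7a (by 1.76 ± 0.21), Tnfrsf11a (by 1.61 ± 0.28), Serpinb6a (by 1.47 ± 0.25) and Ndfip2 (by 1.31 ± 0.19).

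These genes changed in the same direction in 6 of 6 tumors, the library labelled Kit-W/sh tumor 2 included. Of 869 genes, edgeR called 345, 182 higher and 163 lower, 263 of them by at least 2-fold, and DESeq2 called 387 (212 and 175). For 506 genes the groups did not overlap (58.2%, against 7.14% by chance). The share of calls on the higher side was 52.8% with TMM scaling, 70.1% with unscaled library totals (253 higher, 108 lower), 61.1% with reference genes (110 and 70) and 70% with the 9 last-listed genes (240 and 103). With reference genes 180 genes were called, without preneoplastic sample 1 132 and without preneoplastic sample 2 159, where the remaining sample is assumed to vary like the other groups. Of 8 mast cell genes, Hdc alone passed over all genes and adjusted over the list alone (fry adjusted p = 0.495). Kit was at -0.18 ± 0.62 (adjusted p = 0.8287), and Cpa3, at 0 in both preneoplastic samples, owed most of its tumor mean to the library labelled Kit-W/sh tumor 2.

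Monocyte and macrophage genes rose in Kit-W/sh tumors, with 14 higher and 1 lower of 16 both over all genes and adjusted over the list alone. The integrin Itgam rose from 20.3 ± 0.529 to 220 ± 27.8 CPM, the scavenger receptor Msr1 by 2.41 ± 0.55 and the Fc receptor Fcgr3 by 1.85 ± 0.45. Neutrophil genes rose (8 of 9 over all genes, 9 adjusted over the list alone), including Fpr2 from 8.18 ± 3.78 to 179 ± 42.2 CPM and Cxcl5 from 336 ± 105 to 8509 ± 3106 CPM. MHC class I genes fell (7 lower and 1 higher of 15, both over all genes and adjusted over the list alone), among them H2-Q2 (by 2.35 ± 0.54), Psmb9 (by 1.70 ± 0.46) and the chaperone Calr (by 2.00 ± 0.49). In the apoptosis and p53 list, caspase 1 (Casp1, which processes interleukin 1), Fas and Casp8 fell by 1.87 ± 0.35, 1.05 ± 0.26 and 0.50 ± 0.14 and the survival gene Bcl2l1 rose by 0.79 ± 0.17 (3 lower and 1 higher of 6 both over all genes and adjusted over the list alone). Cytotoxic lymphocyte genes fell (5 lower and 1 higher of 13 both over all genes and adjusted over the list alone), with Ccl5 going from 274 ± 124 to 50.5 ± 22.2 CPM, Gzma (granzyme A) from 132 ± 91.7 to 27.7 ± 14.4 CPM, and Klrd1 and Xcl1 lower by 2.11 ± 0.49 and 2.87 ± 0.73. MHC class II genes fell (4 of 8 over all genes, 5 adjusted over the list alone), with H2-Aa lower by 2.02 ± 0.44 and the protease Ctss by 1.25 ± 0.32.

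The fry adjusted p was 0.00457 for each of the macrophage, neutrophil and MHC class I lists, 0.00653 for apoptosis and p53, 0.0136 for cytotoxic lymphocytes and 0.0251 for MHC class II. The camera adjusted p with an estimated correlation was 0.485 for the macrophage and neutrophil lists and 0.637 for the other 4. These 6 called lists of 24 became 1 (neutrophil) with reference-gene scaling, 14 in a fit of the Kit-W/sh groups alone and 3 (macrophage, neutrophil and MHC class I) without preneoplastic sample 1. The 4 lists that fell (MHC class I, MHC class II, cytotoxic lymphocyte, and apoptosis and p53) depended on the scaling. With unscaled library totals, and with the 9 last-listed genes, 4 lists were called higher (macrophage, neutrophil, endothelium, and proliferation and Wnt targets) and 0 lower. Interferon response genes were just short of a call (7 lower and 1 higher of 20 both over all genes and adjusted over the list alone, fry adjusted p = 0.0507). All 11 tested B cell genes were on the lower side (1 lower over all genes, 1 adjusted over the list alone, fry adjusted p = 0.102). Epcam was at -0.08 ± 0.18 (adjusted p = 0.752).

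The stage changes of both genotypes ran in parallel. Among 869 genes, 138 were called higher in tumors in both genotypes where 40.4 were expected for independent lists, 105 were called lower in both where 30.8 were expected, and 0 were called in opposite directions. Arg1, Abcc4, Fam3c, Wfdc18, Neto2 and Cxcr2 were among the shared higher genes, and Trat1, Oas1g, H2-Q1, Lime1 and Zc3h7a among the shared lower genes. Of the 459 genes called in at least 1 genotype, 444 (96.7%) had the same sign in both, and log2 fold changes correlated across genes with Pearson's r of 0.871 and Spearman's rho of 0.842. The comparisons share no libraries, but both come from 1 fit in which all groups share 1 estimate of spread. They also share the scaling and the stage-linked differences in age and dosing, and genes are not independent replicates. The numbers expected for independent lists are therefore only a rough reference.

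**Figure D3:**
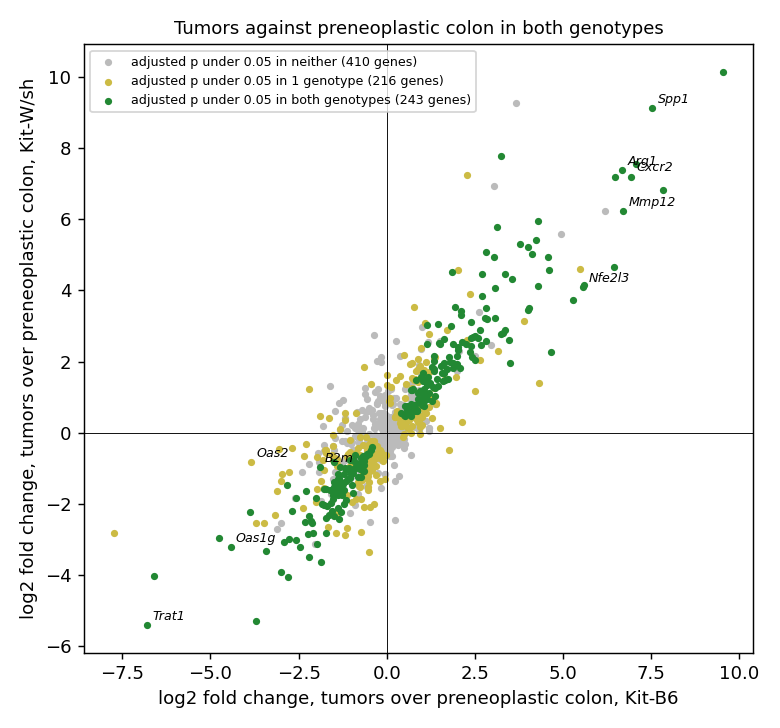
Log2 fold change of tumors over preneoplastic colon for 869 genes, in Kit-B6 mice (horizontal axis) and Kit-W/sh mice (vertical axis), colored by the number of genotypes in which the edgeR adjusted p was under 0.05. In both genotypes 243 genes passed, 216 passed in 1 genotype and 410 in neither, and the position of genes with no preneoplastic counts depends on the fitted prior.

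The interaction test asked whether the genotype difference itself differed between tumors and preneoplastic colon. The non-classical MHC gene H2-T24 had the smallest p, with 644 ± 425 CPM in Kit-B6 preneoplastic colon, 119 ± 6.2 CPM in Kit-W/sh preneoplastic colon, and 77.9 ± 27.8 and 85.3 ± 26.8 CPM in Kit-B6 and Kit-W/sh tumors (interaction 2.58 ± 0.63, adjusted p = 0.515). Galectin 9 (Lgals9) followed with 1.41 ± 0.36 (adjusted p = 0.515), the eosinophil chemokine receptor Ccr3 with 3.44 ± 0.93 (adjusted p = 0.561), and Oas2 with 3.00 ± 0.90, Oas3 with 2.25 ± 0.81 and the epithelial cytokine Il18 with -1.67 ± 0.51 (adjusted p = 0.66 each). Irf7 gave 1.30 ± 0.76 (adjusted p = 0.733), so its fall with stage in Kit-B6 (by 1.99 ± 0.47, adjusted p = 0.00379) and its value in Kit-W/sh (-0.69 ± 0.55, adjusted p = 0.321) were not shown to differ. In all, edgeR called 0 of 869 genes, with 63 at an unadjusted p under 0.05 where 43 were expected, and DESeq2 called 1, H2-T24. Without Kit-B6 preneoplastic sample 1 edgeR called 2, H2-T24 and Gpc4.

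Of the lists, all 5 eosinophil and basophil genes had a positive interaction, with a median of 2.01, 0 passing over all genes and 1 (Ccr3) adjusted over the list alone (fry adjusted p = 0.375). The apoptosis and p53 list (fry adjusted p = 0.542) and the growth signalling list, negative in 5 of 5 genes (fry adjusted p = 0.542), came next. The other lists called in 1 genotype only (interferon response, B cell, macrophage and cytotoxic lymphocyte) had an interaction adjusted p of 0.884 each by fry, so their stage changes were not shown to differ between genotypes. The fry test called 0 of 24 lists with 2 at an unadjusted p under 0.05, camera with a preset correlation called 1 (eosinophil and basophil) and with an estimated correlation 0.

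Of the reference genes, Tfrc and Rpl13a alone were measured, so scaling by reference genes is sensitive to a change in either. Neither passed in any comparison: Tfrc lay between 0.06 ± 0.15 and 0.27 ± 0.41 in the 4 comparisons of groups and Rpl13a between -0.51 ± 0.22 (Kit-W/sh stage, adjusted p = 0.0772) and 0.04 ± 0.24. Relative to TMM, unscaled library totals shifted the median of all genes by 0.25 (log2) in both stage comparisons, reference genes by 0.19 in Kit-B6 and 0.17 in Kit-W/sh, and the 9 last-listed genes by 0.23 in the Kit-W/sh stage comparison, -0.15 in the preneoplastic genotype comparison and 0.14 in the interaction. No called gene changed sign under any of these scalings.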

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

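Of the tests in this part, the swap, carry-over, scaling and follicle tests were chosen after the results were seen, while those for a single wrong label and for admixed mucosa had predictions written beforehand. For each named gene, the lowest or highest tumor of a group was compared with the rest by a Dixon ratio on log2 levels. Of 226 such groups 29 exceeded the limit that chance passes in about 1 in 20, where 11.3 were expected. The groups reuse the same tumors over related genes, and 11 of the 29 were in Kit-B6 tumor 4, so this count is not a test against chance.

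The library labelled Kit-W/sh tumor 2 had 54 CPM of Tpsab1 and 27.8 CPM of Ms4a2, where the other 5 Kit-W/sh tumors had at most 2.26 CPM of each. A swap with a Kit-B6 tumor found no clear partner. Kit, Cpa3 and Tpsb2 were all as low as in the other Kit-W/sh tumors in 0 Kit-B6 tumors. Kit-B6 tumor 3 came near, at 137, 11.6 and 16.8 CPM against their highest values of 99.5, 9.81 and 30.8 CPM, so a swap is not excluded. Carry-over mixes libraries and cannot lift a transcript above its source, and Cpa3, Tpsab1 and Ms4a2, picked because they were the highest of the series, were 1.80, 1.46 and 5.97 times the highest of the other 16 libraries, while Kit, Tpsb2 and Hpgds lay below another library. A single wrong label is consistent with 81.3% of 150 genotype-separating genes lying nearer to the Kit-B6 mean, against at most 40.4% for the other Kit-W/sh tumors, although the 6 Kit-B6 tumors themselves spanned 37.1% to 72.8%. Mast cells in a correctly labelled Kit-W/sh tumor may explain the same values and could not be tested. The Hdc of this library, 118 CPM, was close both to the highest Kit-B6 tumor (112 CPM) and to the lowest Kit-W/sh tumor (108 CPM). Hdc therefore does not decide between the labels.

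Kit-B6 tumor 4 was low in neutrophil and inflammatory genes, at 1.03 CPM of Csf2, 35 of Cxcl1, 39.1 of Cxcl2, 704 of Cxcl5, 29.8 of Cxcr2, 2.06 of Fpr1, 14.4 of Fpr2, 92.6 of Il1b, 169 of Il33, 45.3 of Itgam and 59.7 of Nos2. Its Csf2 and Fpr1 lay below the floor of that library (3 counts, 2.92 CPM before TMM scaling). Admixed non-tumor mucosa should give the same share from both gene sets. Genes higher in tumors gave a median of 86.3% and genes higher in preneoplastic colon 2.77%, a difference of 83.5 points, so the prediction was not met. The 31 genes of the first set ranged from 21.5% (Abcc4) to 102% (Cxcl1). That set held Cxcl1, Cxcl2, Cxcl5, Cxcr2, Il1b and Il33, for which this tumor stood apart, so its median is not independent of that pattern. The 14 genes of the second set ranged from -11.2% (Ms4a1) to 44.6% (Zbtb16), with Car4 at 26.8%, so the ranges of the 2 sets overlapped. The reference was colon of postnatal week 14, not mucosa of week 32, so the test cannot decide on admixture and a share may remain. In the same comparison Kit-B6 tumor 2 gave medians of 33.7% and 44.1% with overlapping quartiles (5.18 to 55.1 and 2.95 to 69.2), so admixed mucosa stays open for that tumor. A tumor with little myeloid infiltrate may be the cause and could not be tested without histology.

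In preneoplastic colon Irf7, Sp100, Oas2 and Oas3 had lower averages in Kit-W/sh samples. Scaling is an unlikely cause, since the largest shift of the median gene among 5 scalings was -0.15 log2, too small to produce the median of these 4 genes, which were picked for their small p and stayed at -2.37 or further from 0. Lymphoid follicles in the Kit-B6 samples could not be excluded: in Kit-B6 sample 1, the only one with B cell genes no higher than in Kit-W/sh, the 4 genes were at a median of 2.81 times the higher Kit-W/sh sample.

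Kit-B6 tumor 2 was high in the B cell genes Bank1 (165 CPM, others up to 23.5), Ms4a1 (247, others up to 7.35) and Pax5 (86.6, others up to 2.1). The same tumor was high in Ccl5 (134 CPM, others 34.7 to 57) and in Il22 (4.19 CPM, from 3 counts). Kit-B6 tumor 3 was high in Hells (517 CPM, others 353 to 370) and Neto2 (1300 CPM, others 405 to 623) and had 0 CPM of Trat1 (others 2.42 to 4.72). Kit-B6 tumor 6 was high in Bcl2l1 (2490 CPM, others 1730 to 1970). Kit-B6 tumor 1 was low in Ccr3 (1.62 CPM) and Kit-B6 tumor 5 high in Hpgds (525 CPM, others 124 to 190). Ccr3 and Trat1 had at most 6 and 5 counts in any Kit-B6 tumor, near the floor of 3 counts. The library labelled Kit-W/sh tumor 2 was also low in Clcf1 (18.5 CPM, others 30.9 to 41.5) and high in Klrd1 (71.7 CPM, others 16.5 to 24.4). Kit-W/sh tumor 3 was high in Oas1b (50.5 CPM, others 12.8 to 19.6), Kit-W/sh tumor 4 low in Fcgr3 (457 CPM, others 552 to 605) and Kit-W/sh tumor 6 low in Rassf4 (90.7 CPM, others 176 to 247).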

How the results depend on the processing

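The removal of Kit-B6 tumor 4 with the library labelled Kit-W/sh tumor 2 and the size factors from the 9 last-listed genes were chosen after the results were seen. The same holds for some alternatives applied to lists, while reference-gene scaling, the replicate block and single libraries left out were planned for the lists. In tumors, the 0 genes called between genotypes became 27 with DESeq2 and 15 without those 2 libraries, and the 0 lists became 4 by camera with a preset correlation and 1 without those 2 libraries. These 2 libraries were chosen for their unusual mast cell and neutrophil genes, so calls of such genes without them, Cpa3 among the 15 (-4.71 ± 0.99, adjusted p = 0.0351), are not independent of that choice. No single tumor left out gave a call there. In preneoplastic colon, the call of Irf7 gave way to 0 genes with library totals, with size factors from the 9 last-listed genes and with all 17 libraries in 1 fit. DESeq2 called 20 genes there, Irf7 among them. Leaving out 1 library there gave 0 to 16 genes, with 0 without Kit-B6 sample 3 and 16 without Kit-B6 sample 1, and the 0 lists became 1 with library totals and 2 by camera with a preset correlation. For the Kit-B6 stage comparison the 6 lists became 10 with library totals, 0 with reference genes, 0 by camera with an estimated correlation, 3 with the 2 groups alone, 11 with Kit-B6 tumors 4 and 5 summed, 13 without the 2 libraries, and 0 (without preneoplastic sample 2) to 12 (without tumor 4) with 1 library left out. For the Kit-W/sh stage comparison the 345 genes became 180 with reference genes and 132 to 367 with 1 library left out (without preneoplastic sample 1 and without the library labelled Kit-W/sh tumor 2). Its 6 lists (2 higher, 4 lower) became 4 higher and 0 lower both with library totals and with the 9 last-listed genes, so no list that fell kept its call, 1 with reference genes, 0 by camera with an estimated correlation, 14 with the 2 groups alone, 12 with Kit-B6 tumors 4 and 5 summed, 14 without the 2 libraries and 3 to 7 with 1 library left out. The interaction gave 1 gene with DESeq2, 0 to 2 genes with 1 library left out and 1 list by camera with a preset correlation. With the sample number as a replicate block, 0 genes were called in preneoplastic colon. The same block gave 276 genes in the Kit-B6 stage comparison and 0 lists in the Kit-W/sh stage comparison. Of the Kit-B6 tumors, 3 of 6 correlated best with the Kit-W/sh tumor of the same number (correlations -0.195 to 0.39). Whether the numbers pair samples was therefore not settled. For 42 named genes called in the Kit-B6 stage comparison, 755 of 798 values over 19 settings kept the call. For 45 in Kit-W/sh, 777 of 810 values over 18 settings did, and 0 reversed sign in either. The call held in every setting for 34 of the 42 and 32 of the 45 genes. Most of these genes were picked for their small p in the same data, so their stability does not extend to all called genes. The cause of the shifts between settings was not tested.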

Other observations

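Car4 and the overlap of genotype differences between stages were chosen after the results were seen, while the split tests at the end had predictions written beforehand. Beyond the neutrophil genes, single checkpoint, T cell and stromal genes changed in tumors of both genotypes, although none of these lists was called as a whole. The checkpoint ligands Vtcn1 (B7-H4) and Cd276 (B7-H3) rose by 3.48 ± 0.54 and 2.15 ± 0.35 in Kit-B6 mice (edgeR adjusted p = 0.0001676 and 0.0001969) and by 2.62 ± 0.61 and 2.55 ± 0.42 in Kit-W/sh mice (adjusted p = 0.003838 and 0.0004617), in 6 of 6 tumors each. Cd160, a receptor of cytotoxic lymphocytes, fell by 2.90 ± 0.65 and 3.07 ± 0.69. Of 21 checkpoint genes 3 were higher and 4 lower in Kit-B6 tumors (2 and 4 adjusted over the list alone, fry adjusted p = 0.602) and 4 higher and 2 lower in Kit-W/sh tumors (4 and 2 adjusted over the list alone, fry adjusted p = 0.564). The kinase Zap70 rose by 2.46 ± 0.49 and 2.69 ± 0.59 while Cd7 fell by 1.68 ± 0.46 and 2.08 ± 0.50. Of 15 pan T cell genes 1 was higher and 3 lower in Kit-B6 tumors, the same adjusted over the list alone (fry adjusted p = 0.126), and 1 was higher and 1 lower in Kit-W/sh tumors, the same adjusted over the list alone (fry adjusted p = 0.584). The costimulatory receptor Tnfrsf9 (4-1BB), of the regulatory T cell list, rose by 4.58 ± 0.91 and 4.96 ± 1.05 (that list 2 higher of 13, 1 adjusted over the list alone, fry adjusted p = 0.463 in Kit-B6, and 3 higher, 2 adjusted over the list alone, fry adjusted p = 0.105 in Kit-W/sh).

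Among stromal genes, fibronectin (Fn1) rose by 2.67 ± 0.51 in Kit-B6 and 2.46 ± 0.60 in Kit-W/sh tumors, collagen Col3a1 by 1.46 ± 0.37 and 1.30 ± 0.43, and Fap, a fibroblast protease, fell by 1.65 ± 0.39 and 2.33 ± 0.43. Of 9 stromal genes 4 were higher and 2 lower in Kit-B6 tumors (5 and 2 adjusted over the list alone, fry adjusted p = 0.491) and 5 higher and 3 lower in Kit-W/sh tumors, the same adjusted over the list alone (fry adjusted p = 0.584). The endothelial adhesion genes Icam1 and Selp rose by 2.40 ± 0.41 and 2.78 ± 0.62 in Kit-B6 and by 2.67 ± 0.49 and 3.23 ± 0.72 in Kit-W/sh tumors. Of 10 endothelial genes 3 were higher and 1 lower in Kit-B6 (fry adjusted p = 0.0843) and 4 higher in Kit-W/sh (fry adjusted p = 0.0507), the same counts adjusted over the list alone. Chemokine genes changed in both directions: Cxcl3 went from 2.33 ± 2.8 to 217 ± 150 CPM in Kit-B6, while of 23 chemokine ligands 10 were higher and 3 lower in Kit-B6 (10 and 4 adjusted over the list alone, fry adjusted p = 0.591) and 10 higher and 4 lower in Kit-W/sh, the same adjusted over the list alone (fry adjusted p = 0.496). Car4, a carbonic anhydrase of surface colonocytes, fell by 3.71 ± 1.15 in Kit-B6 (adjusted p = 0.0176) and by 5.30 ± 1.26 in Kit-W/sh (adjusted p = 0.0045).

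The remaining lists had no call in the Kit-B6 stage comparison. There the fry adjusted p was 0.475 for inflammatory cytokines (4 higher and 1 lower of 10), 0.591 for type 2 immunity (3 and 1 of 7), 0.555 for type 17 immunity (2 and 1 of 7), 0.762 for Toll-like receptor and NF-kB genes (3 and 1 of 10), 0.555 for dendritic cells (1 and 1 of 6), 0.491 for epithelium (1 and 1 of 3), 0.211 for proliferation and Wnt targets (1 and 0 of 3), 0.302 for apoptosis and p53 (2 and 3 of 6) and 0.555 for growth signalling (1 and 0 of 5), and adjusted over the list alone the counts were the same. The Toll-like receptor and NF-kB list had a median of -0.01 and a mean of 0.08 with an upward test. The epithelium list had a median of 0.02 and a mean of 0.35 with a downward test. In the Kit-W/sh stage comparison, only apoptosis and p53 was called among these lists. Proliferation and Wnt targets were just short of a call there (1 higher of 3, fry adjusted p = 0.0507). The others lay between 0.0967 (type 2 immunity) and 0.584 (Toll-like receptor and NF-kB) by fry.

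Genotype differences at the 2 stages, which share no libraries, were weakly related (Pearson's r of 0.186, Spearman's rho of 0.112 over 745 genes). At an unadjusted p under 0.05, 49 genes in tumors and 30 in preneoplastic colon were on the higher side in Kit-W/sh, and 8 were in both where 1.97 were expected: Calr, Ccl2, Cd14, Cxcl1, Cxcl2, Nfkbia, Srsf7 and Tnf. Nfkbia differed by 0.71 ± 0.24 in tumors and 0.79 ± 0.17 in preneoplastic colon and Ccl2 by 1.19 ± 0.54 and 1.14 ± 0.39, without passing the adjustment at either stage. On the lower side 3 genes (Emp1, Kit and Mef2c) were in both where 2.53 were expected. Both expected numbers assume independent genes, which these are not, so they are only a rough reference.

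Relabelling the libraries showed what chance can give. For the tumor genotype comparison, 8 of 100 drawn splits, the real one included, gave as many genes at an unadjusted p under 0.05 as the real 109 (highest other 161), so chance cannot be excluded. For the called genes and lists the real counts were 0, which 100 of 100 splits must reach (highest other 8 genes and 1 list), so these 2 counts test nothing. For the Kit-B6 stage comparison 1 of 84 splits, the real one, gave 357 genes (highest other 140). This is the smallest share these splits allow, so chance is unlikely for the genes if the libraries are independent. For its lists 5 of 84 splits, the real one included, gave as many as the real 6 (highest other 8), so chance cannot be excluded.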
